A study of Mus musculus with 49 samples.

How the data were processed

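RNA sequencing of mouse small-intestinal crypt cells was analysed from 25 libraries in 12 groups, and the other 24 of 49 samples were not analysed. Per the labels, RNA was sequenced as 75 bp single-end reads on a NextSeq 500. Libraries were made with a SMART-Seq v4 kit, except that both libraries of crypts labelled Rbpj-deleted and replicate 1 of the CD274+CD69+ control cells were labelled as TruSeq. Per the labels' protocols, cells of the Bmi1-GFP and Lgr5-GFP lines were released with TrypLE, cells sorted on CD24 or on CD274 and CD69 with Dispase, and no enzyme was stated for the unsorted crypts. The labels call the replicates biological and do not say which share a mouse, a litter or a day.

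The deposited file used here is a table of raw read counts per gene for all 25 libraries, with 24062 gene symbols. Per the submitters' processing notes the tools were Bowtie2, TopHat2 2.0.6 and DESeq2 and the genome build was mm10; which step used which tool, the counting program, the gene annotation and the strand setting are not given in the sources used here. The deposited counts were whole numbers that summed to between 11179085 and 27371108 per library, so they were treated as raw counts with no normalization by the authors. Each of the 25 columns was matched to its sample by name, and 0 columns were left unmatched. Of the 14837 genes tested, 13984 matched a RefSeq symbol of GRCm38.p6, the assembly that mm10 denotes, and 14786 matched once synonyms were allowed; coordinates are those of that annotation. The symbols Clca3 and Siglec5 of the table are the older symbols of Clca1 and Siglecf. Reads of the alpha-defensin genes (Defa) can be shared between near-identical copies, and without a stated strand setting genes that overlap cannot be separated, so values of single defensins are uncertain.

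Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and 1 quasi-likelihood model was fitted over the 24 libraries of the 11 groups that have 2 or 3 libraries, so that all groups share an estimate of the spread (common dispersion 0.0714, prior degrees of freedom 5.44). A gene was called when its Benjamini-Hochberg adjusted p was below 0.05, adjusted over all genes tested within a comparison. Every adjusted p for a gene is from this edgeR model. Levels are TMM-scaled CPM, the counts of a gene relative to the library total, given as mean ± SD with the number of libraries; the log2 fold change is the fitted value with its standard error (SE). No fold is given where a group holds 3 counts or fewer of a gene. The mature secretory groups were each compared with the mean of the other 2 on the log scale. The SD of that pooled side spans 2 cell types, and a difference can come from 1 of them.

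Gene lists for 18 cell types, states and pathways were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 18 lists within each comparison, and again with a correlation estimated from the residuals (adjusted p marked estimated). Of 102 list tests assigned to a comparison, 62 passed at an adjusted p below 0.05 and 11 passed with the estimated correlation. The lists were stem cell, reported +4 cell markers, proliferation, enterocyte, goblet, Paneth, enteroendocrine hormones, enteroendocrine transcription factors, neuroendocrine secretory granule, secretory precursor, Notch target, tuft, immune cell, stromal and endothelial, p53 target, regeneration, interferon response, and immediate early and heat shock. Fer1l6, Mln and Sh2d6 were on a list and were not found in the table under those symbols. Members of a list not given as higher or lower were not called. A list's count "by list alone" repeats the adjustment over its members only.

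The comparisons, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule names the reporter, sorted or targeted genes; the 5 largest changes per direction (3 in secondary comparisons) among called genes with a mean of 20 CPM or more in the higher group and no overlap between libraries, unnamed gene models left out; and for each assigned list up to 3 called members (2 in secondary comparisons) of lowest adjusted p, with the most expressed member that was not called. Genes outside it are said to be chosen after their values were seen. Some genes that the rule names are left out of the text for length, a choice made after their values were seen, and others are not reported here.

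The single irradiated library has no replicate, so it was given no test. Its log2 CPM, with a prior count of 2, was set against the mean log2 CPM of the 3 unirradiated libraries, and a gene was described as outside their range when it lay beyond the lowest or highest of them by more than 1 on the log2 scale with 1 CPM or more on either side. List medians were placed among 10000 random lists of the same size matched on mean expression in 20 bins.

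The model was tested on simulated counts with 200 changed genes, and rates may not hold for low or variable genes. For Bmi1-GFP against Lgr5-GFP-Cre over 14451 genes, 56% and 98% of genes changed by a fold of 2 and 4 were found, with 7 false calls among 161. With 2 libraries a group, as for CD274+CD69+ cells over 14648 genes, these shares were 33% and 96%, with 7 false calls among 136. The rule for the irradiated library described 92 and 100 of 100 genes changed by a fold of 4 and 8, and 1.9% of unchanged genes.

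Alternatives were scaling by DESeq2's size factors, no filter on low counts, DESeq2 1.42.0 in place of edgeR, a fit on the compared groups only, an added limit of 1 on the absolute log2 fold change, the replicate number as a block, the kit as a covariate where it varied, and each library left out in turn. When a library of a group of 2 is left out, the lone library is assumed to vary like the other groups. For the irradiated library a prior count of 0.5 was also tried. Chosen after seeing the data were a count without genes on the X and Y chromosomes and ratios of the irradiated library centred on the median gene.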

Results

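Libraries sorted as Paneth, goblet and Lgr5 stem cells carried known marker genes of those cell types. Lyz1, the lysozyme of Paneth cell granules, stood at 163000 ± 44900 CPM in Paneth cells (n = 2), and Muc2, the gel-forming mucin of goblet cells, at 4830 and 5280 CPM in the 2 goblet libraries. Olfm4, a marker of crypt base stem cells, ranged from 4130 to 5800 CPM in the 3 Lgr5-GFP-Cre libraries and stood at 1.73 and 4.12 CPM in goblet libraries. On the first 2 principal components (30.3% and 17.2% of the variance) goblet libraries lay at 162.9 and 171.6 on the first, Lgr5-GFP libraries of both lines between -114.7 and -74.7, and enteroendocrine libraries at -142.3 and -121.9 on the second.

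**Figure D1:**
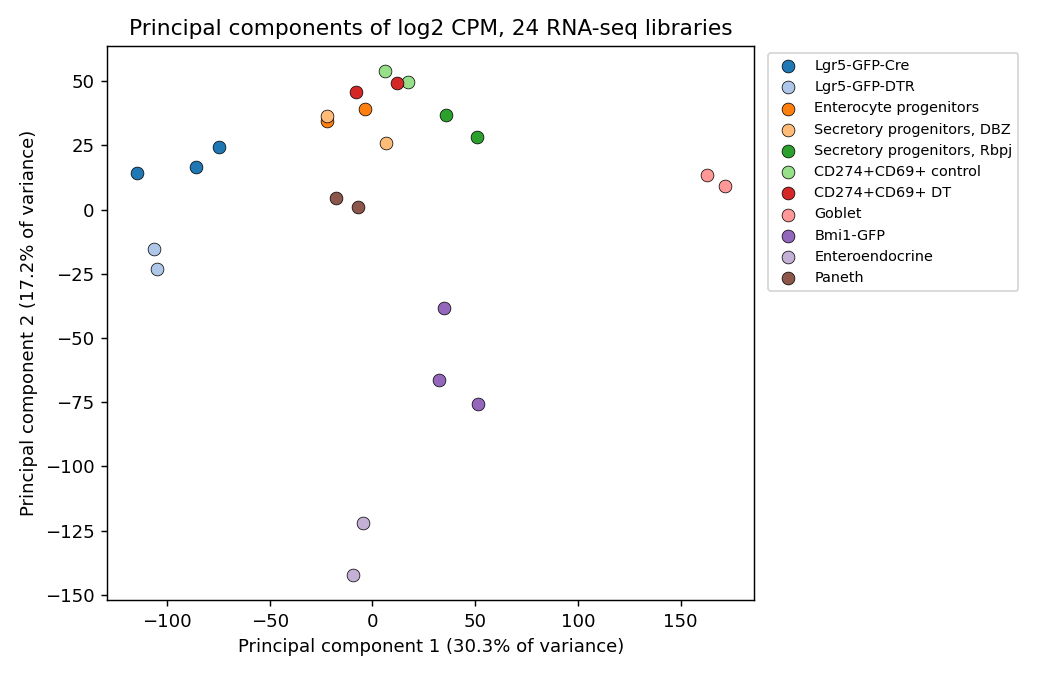
First and second principal components of log2 CPM for the 24 libraries of the 11 replicated groups, with the share of variance on each axis. Each point is 1 library, coloured by group.

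**Figure D2:**
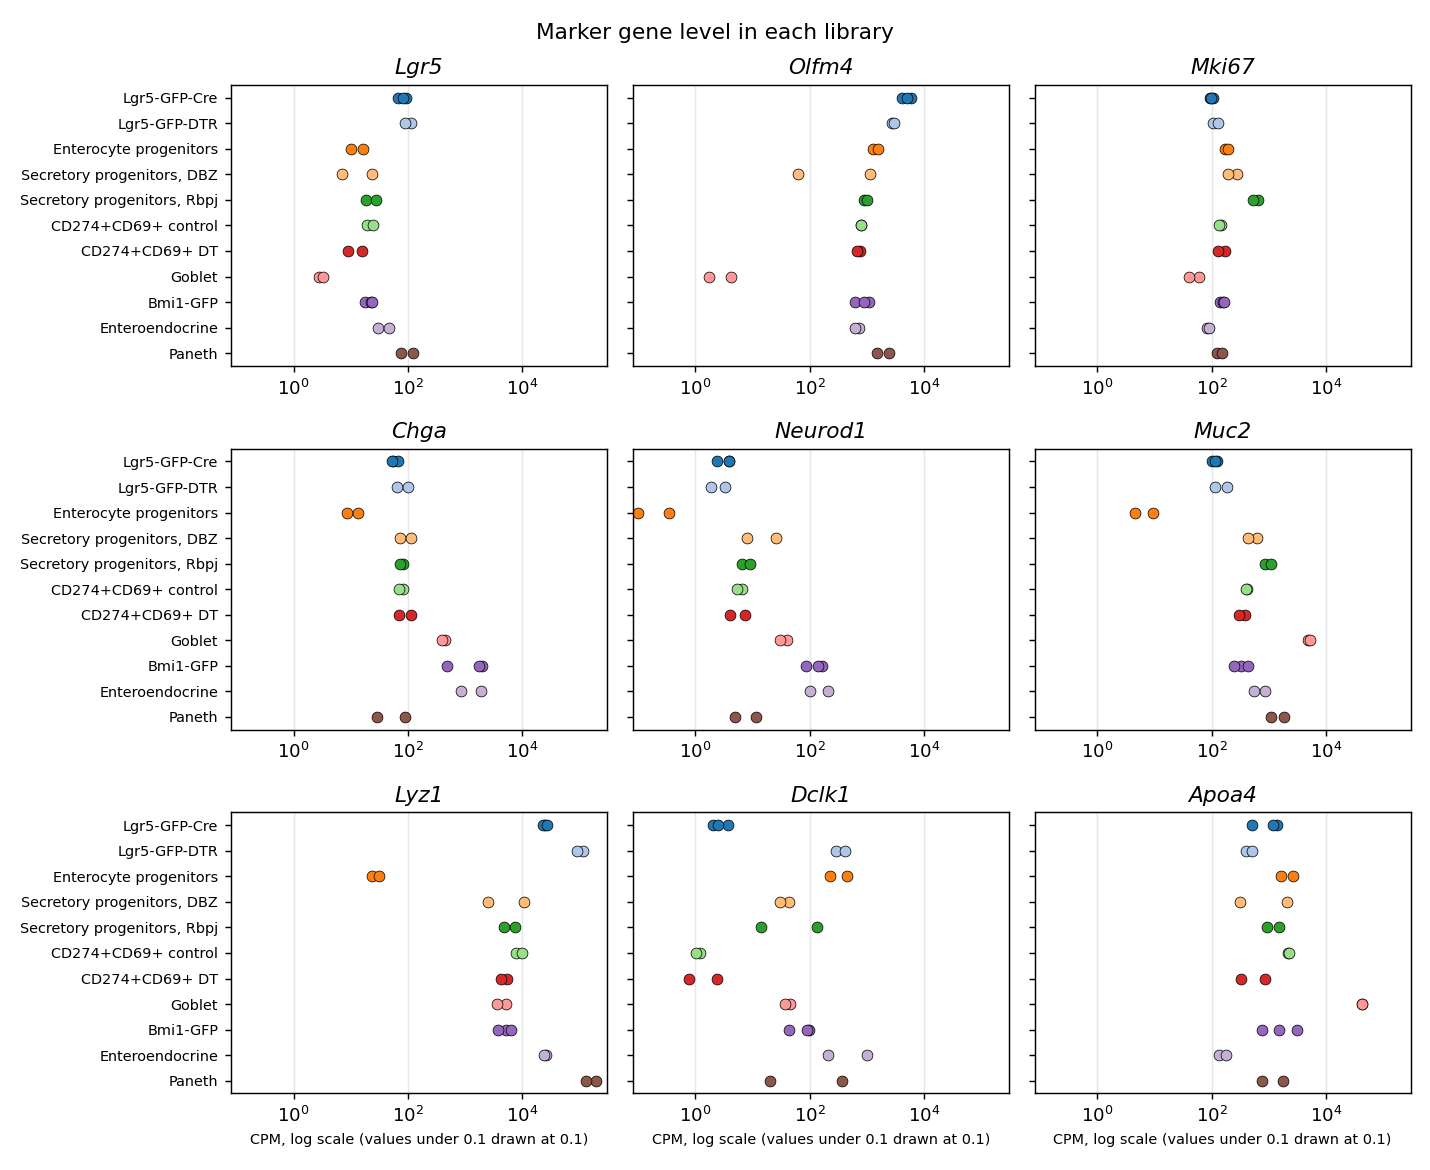
CPM of 9 marker genes per library on a log scale, in 11 groups, with values under 0.1 drawn at 0.1. Each point is 1 library, and Lyz1 stood at 163000 ± 44900 CPM in Paneth cells (n = 2).

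Paneth cells were compared with goblet and enteroendocrine cells as a pair of groups (2 libraries each). The lysozyme gene Lyz1 (163000 ± 44900 against 14700 ± 11900 CPM, log2 3.96, SE 0.4, adjusted p = 2.14e-06) and the defensin gene Defa24 (9820 ± 5460 against 2120 ± 2500 CPM, log2 4.42, SE 0.42, adjusted p = 1.15e-06) were higher in Paneth cells. 14 of 15 Paneth genes were higher (median log2 3.06, camera adjusted p = 8.62e-12, 0.0929 estimated). The counts of this and other lists were the same by list alone, except where given. Defa21 and Defa22 (log2 6.04, SE 1.07 and log2 5.48, SE 1.03) were among the genes of greatest difference. Pnliprp2, a pancreatic-type lipase on the Paneth list, was not called (2240 ± 85.7 against 2000 ± 2050 CPM, adjusted p = 0.335). The incretin gene Gip (log2 -4.34, SE 0.6, adjusted p = 3.22e-05) and the granin Chgb (log2 -3.36, SE 0.49, adjusted p = 6.13e-05) were lower in Paneth cells. 8 of 13 enteroendocrine hormone genes were lower (0 higher and 9 lower by list alone, median log2 -1.75, camera adjusted p = 4.17e-06, 0.164 estimated). 3 of 17 goblet genes were higher and 2 lower (3 higher and 3 lower by list alone, median log2 -0.11, camera adjusted p = 0.468). The lyase gene Npl was lower too (log2 -5.63, SE 1.09). Cd24a, which encodes the sorted antigen CD24, was not called (1570 ± 159 against 1720 ± 1090 CPM, adjusted p = 0.943). In all 5057 genes were called, 3066 higher and 1991 lower. With DESeq2's size factors, which shifted the median gene by -0.11, 2514 were higher and 2339 lower, and DESeq2 called 2632 and 2630.

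Goblet libraries, sorted as CD274+CD69+ late after the Notch inhibitor dibenzazepine (DBZ), held secretory and absorptive transcripts, and a mixed sort was not tested. The chloride channel regulator Clca3 (35300 ± 16800 against 660 ± 551 CPM, log2 6.19, SE 0.5, adjusted p = 1.14e-08) was higher than in Paneth and enteroendocrine cells, and so was the brush border peptidase Anpep (12600 ± 4940 against 306 ± 261 CPM, log2 5.79, SE 0.44, adjusted p = 5.1e-09). 20 of 20 enterocyte genes were higher (median log2 4.22, camera adjusted p = 4.94e-11, 0.364 estimated). Dpp4 stood at 2270 ± 271 against 161 ± 118 CPM. The lipid carrier gene Apoa4 stood at 43400 and 42400 CPM in the 2 goblet libraries. 8 of 17 goblet genes were higher and 3 lower (median log2 0.68, camera adjusted p = 0.0356, 0.605 estimated). Tff3 was not called (adjusted p = 0.166). 1 of 15 Paneth genes was higher and 13 lower (median log2 -3.59, camera adjusted p = 0.00102, 0.542 estimated). 1 of 13 enteroendocrine hormone genes was higher and 6 lower (1 higher and 5 lower by list alone, median log2 -0.83, camera adjusted p = 0.831). Among hormones, neurotensin, Nts, was higher (287 ± 89 against 8.41 ± 13.9 CPM), and ghrelin, Ghrl, lower (63.7 ± 5.17 against 1180 ± 1320 CPM). Of greatest difference were Pmp22 and Clca6 (log2 13.57, SE 1.11 and log2 13.57, SE 0.99), and on the low side Olfm4 and the orphan nuclear receptor Nr4a1 (log2 -8.6, SE 0.95 and log2 -7.34, SE 0.78). Cd274 and Cd69, the sorted antigens, were low and not called (3.48 ± 0.801 and 0.87 ± 0.227 CPM in goblet cells). Of 8982 genes called, 3931 were higher and 5051 lower. With DESeq2's size factors, which shifted the median gene by 0.2 log2, 4534 were higher and 4433 lower.

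Enteroendocrine cells, sorted as CD24-high and negative for the lectin UEA, were higher than the other mature secretory cells in the hormone genes Ghrl (2280 ± 624 against 67.9 ± 6.77 CPM, log2 5.07, SE 0.36, adjusted p = 6.71e-08) and Gip (12500 ± 6620 against 259 ± 174 CPM, log2 5.88, SE 0.5, adjusted p = 1.76e-07). 10 of 13 enteroendocrine hormone genes were higher and 1 lower (median log2 2.18, camera adjusted p = 0.000188, 0.471 estimated). 16 of 16 enteroendocrine transcription factor genes were higher (median log2 3.69, camera adjusted p = 4.37e-09, 0.409 estimated). Isl1 had log2 4.76 (SE 0.37). The tuft cell genes Plcb2 (log2 3.87, SE 0.57) and Ltc4s (log2 3.72, SE 0.59) were higher. 14 of 16 tuft genes were higher (median log2 3.1, camera adjusted p = 0.0118, 0.742 estimated). Their replicates differed in Dclk1, at 204 and 985 CPM. Interleukin genes Il1b (77.2 ± 37.9 CPM) and Il1r2 (79.1 ± 41.5 CPM) stood at 0 and 0.0184 ± 0.0368 CPM in the other cells. 2 of 17 goblet genes were higher and 6 lower (median log2 -0.4, camera adjusted p = 0.0143, 0.606 estimated). Clca3 and the secretory granule gene Sytl2 were lower (log2 -4.89, SE 0.62 and log2 -3.3, SE 0.42). Cd24a was higher (2520 ± 989 against 1240 ± 387 CPM, adjusted p = 0.00587), a call lost without enteroendocrine replicate 2. In total 8243 genes were called, 4963 higher and 3280 lower.

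Cells sorted for Bmi1-GFP were compared with Lgr5-GFP-Cre cells (3 libraries each). The gut hormones Cck (2270 ± 336 against 31.2 ± 10.4 CPM, log2 6.19, SE 0.38, adjusted p = 6.53e-09) and Ghrl (2660 ± 280 against 20.2 ± 5.15 CPM, log2 7.04, SE 0.43, adjusted p = 6.53e-09) were higher in Bmi1-GFP cells. The Wnt target Sp5 (12.8 ± 1.8 against 78.4 ± 17.3 CPM, log2 -2.61, SE 0.25, adjusted p = 9.78e-07) was lower. Bmi1, the Polycomb gene of the reporter, was slightly higher (24.5 ± 2.72 against 19.1 ± 1.02 CPM, log2 0.36, SE 0.14, adjusted p = 0.0446), and Lgr5 was lower (21 ± 3.16 against 80.2 ± 13.8 CPM, log2 -1.93, SE 0.35, adjusted p = 0.00026). The Bmi1 call was lost with no filter, on the compared groups only and without Lgr5-GFP-Cre replicate 1 or 3 or Bmi1-GFP replicate 2 or 3.

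13 of 13 enteroendocrine hormone genes were higher (median log2 5.75, camera adjusted p = 5.91e-19, 0.016 estimated). Secretin, Sct, was among them (log2 5.75, SE 0.46). 16 of 16 secretory granule genes were higher (median log2 4.25, camera adjusted p = 4.06e-18, 0.0147 estimated). The granin Scg2 (log2 7.49, SE 0.33), the carboxypeptidase Cpe (log2 5.48, SE 0.36) and the prohormone convertase Pcsk1 (log2 4.25, SE 0.34) were of lowest adjusted p. 12 of 16 enteroendocrine transcription factor genes were higher and 1 lower (median log2 4, camera adjusted p = 6.26e-08, 0.152 estimated). Isl1 (log2 4.38, SE 0.4) and Pax6 (log2 5.91, SE 0.52) were higher, Etv1 stood at 44.7 ± 11.7 against 0.0643 ± 0.111 CPM, and Neurog3, which starts endocrine differentiation, was not called (6.79 ± 4.68 against 13.8 ± 3.94 CPM, adjusted p = 0.162). 15 of 16 tuft genes were higher (median log2 4.4, camera adjusted p = 1.9e-05, 0.38 estimated). Plcb2 and the cyclooxygenase gene Ptgs1 had log2 5.02 (SE 0.73) and 4.67 (SE 0.9), while Pou2f3 was not called (adjusted p = 0.125).

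19 of 21 stem cell genes were lower (median log2 -1.93, camera adjusted p = 7.24e-14, 0.0925 estimated). Igfbp4 (log2 -2.85, SE 0.27) and Smoc2 (log2 -2.17, SE 0.23) were lower, and Prom1 was not called (185 ± 66.5 against 275 ± 105 CPM, adjusted p = 0.104). 1 of 27 proliferation genes was higher and 20 lower (median log2 -0.85, camera adjusted p = 2.87e-06, 0.32 estimated). The replication helicase genes Mcm2 (log2 -1.72, SE 0.21, adjusted p = 7.28e-06), Mcm5 (log2 -1.64, SE 0.21) and Mcm3 (log2 -1.15, SE 0.17) were lower, whereas the mitotic gene Top2a was not called (log2 0.33, SE 0.18, adjusted p = 0.138). 1 of 5 reported +4 cell marker genes was higher and 2 lower (median log2 -0.9, camera adjusted p = 0.195). Lrig1 and Hopx were lower (log2 -1.25, SE 0.29 and log2 -0.68, SE 0.17), and Mex3a was not called (adjusted p = 0.146). 1 of 13 secretory precursor genes was higher and 6 lower (median log2 -0.82, camera adjusted p = 0.03, 0.507 estimated). Atoh8, Hes6 and Dll3 were lower (log2 -3.24, SE 0.38, log2 -1.67, SE 0.25 and log2 -3, SE 0.55), and the Notch ligand Dll1 was not called (adjusted p = 0.202). 12 of 15 Paneth genes were lower (median log2 -2.28, camera adjusted p = 2.87e-06, 0.226 estimated). The lectin Itln1 (log2 -2.66, SE 0.44, adjusted p = 0.000115) and the defensins Defa17 (log2 -2.6, SE 0.38) and Defa24 (log2 -2.63, SE 0.41) were lower. 6 of 17 goblet genes were higher and 4 lower (7 higher and 4 lower by list alone, median log2 0.79, camera adjusted p = 0.526). Clca3 (log2 2.61, SE 0.47) and Muc2 (log2 1.55, SE 0.29) were higher and the regulator Foxa3 lower (log2 -2.12, SE 0.33).

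Transcripts of lymphocytes were present in Bmi1-GFP libraries, with the granzyme Gzmb (404 ± 204 against 6.04 ± 0.993 CPM, log2 6.06, SE 0.65, adjusted p = 2.38e-06) and the leukocyte phosphatase Ptprc (log2 6.08, SE 0.7, adjusted p = 4.52e-06). 14 of 16 immune cell genes were higher (15 higher and 0 lower by list alone, median log2 5.06, camera adjusted p = 2.89e-08, 0.152 estimated). That median was 4.84 with genes at 0 held at their bound. Of greatest difference on the high side were Igj (log2 8.77, SE 0.99, adjusted p = 6.31e-06) and Alb (log2 8.92, SE 1.51, adjusted p = 0.000159), albumin, which stood at 113, 3.73 and 3.06 CPM in the 3 libraries. Gast, gastrin, stood at 22.4 ± 26.9 against 0.0146 ± 0.0252 CPM and Qpct at 20 ± 6.78 against 0.0146 ± 0.0252 CPM. On the low side stood Trip6 (log2 -3.71, SE 0.56), Gkn3 (log2 -3.62, SE 0.49), the urea transporter gene Slc14a1 (log2 -3.58, SE 0.42) and Rgcc (log2 -3.55, SE 0.44). Pla2g2a, annotated as a transcribed pseudogene, had log2 -6.63 (SE 1.25) and stood at 7670, 84 and 1130 CPM in the Lgr5-GFP-Cre libraries. Of 14837 genes tested, 7475 were called, 4141 higher and 3334 lower, and 4372 had an absolute log2 fold change of 1 or more.

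Between Bmi1-GFP cells (n = 3) and enteroendocrine cells (n = 2), 24.7% of all genes tested were called. Of 13 enteroendocrine hormone genes 3 were called higher in Bmi1-GFP cells and 1 lower, and 13 of 16 secretory granule genes were not called. Neither list stood far from the share over all genes. The hormone gene Cck (2270 ± 336 against 587 ± 314 CPM, log2 1.95, SE 0.36, adjusted p = 0.00139) was higher in Bmi1-GFP cells and Gip (1550 ± 716 against 12500 ± 6620 CPM, log2 -3.02, SE 0.5, adjusted p = 0.000661) was lower. Bmi1 itself was not called (24.5 ± 2.72 against 27.7 ± 2.7 CPM, adjusted p = 0.424), and Cd24a was lower (451 ± 151 against 2520 ± 989 CPM, log2 -2.48, SE 0.33, adjusted p = 0.00013).

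3 of 13 enteroendocrine hormone genes were higher and 1 lower (3 higher and 2 lower by list alone, median log2 0.4, camera adjusted p = 0.294). Neurotensin, or Nts (198 ± 40.1 against 0.505 ± 0.279 CPM, log2 8.68, SE 1.07, adjusted p = 8.18e-05), was of greatest difference. 1 of 16 secretory granule genes was higher and 2 lower (median log2 -0.07, camera adjusted p = 0.876), the mean being 0.06. Scg2 was higher (log2 2.3, SE 0.29), the calcium sensor Scgn (log2 -1.94, SE 0.39) and Cplx2 (log2 -1.38, SE 0.38) lower, and Cpe not called (545 ± 103 against 514 ± 213 CPM). 1 of 16 enteroendocrine transcription factor genes was higher and 7 lower (1 higher and 8 lower by list alone, median log2 -1.24, camera adjusted p = 0.00584, 0.637 estimated). Isl1 and Neurog3 were lower (log2 -1.89, SE 0.37 and log2 -3.04, SE 0.66), Etv1 higher (log2 2.2, SE 0.53) and Neurod1 not called (adjusted p = 0.763). 1 of 13 secretory precursor genes was higher and 6 lower (1 higher and 7 lower by list alone, median log2 -1.29, camera adjusted p = 0.000778, 0.637 estimated). Dll3, Hes6 and the receptor gene Kit were lower (log2 -3.6, SE 0.58, log2 -1.53, SE 0.27 and log2 -2.04, SE 0.4). 12 of 15 Paneth genes were lower (0 higher and 14 lower by list alone, median log2 -2.94, camera adjusted p = 3.81e-13, 0.223 estimated). Defa17 and the matrix protease Mmp7 were lower (log2 -4.39, SE 0.43 and log2 -2.94, SE 0.43). 1 of 17 goblet genes was higher and 6 lower (1 higher and 7 lower by list alone, median log2 -0.71, camera adjusted p = 0.00217, 0.637 estimated). Spink4 stood at 507 ± 52.6 against 13700 ± 6620 CPM (log2 -4.76, SE 0.5), and Fcgbp was not called (adjusted p = 0.807). 10 of 16 tuft genes were lower (0 higher and 12 lower by list alone, median log2 -2.54, camera adjusted p = 0.00103, 0.637 estimated). Hpgds, Plcb2 and Pou2f3 were lower (log2 -3.83, SE 0.78, log2 -2.99, SE 0.61 and log2 -3.61, SE 0.79). Without enteroendocrine replicate 1 the calls of Scgn, Cplx2, Isl1 and Neurog3 were lost, as was Cplx2 without Bmi1-GFP replicate 2 or 3, and without enteroendocrine replicate 2 those of Etv1 and Plcb2. 1 of 13 immediate early and heat shock genes was lower (median log2 -0.24, camera adjusted p = 0.505).

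7 of 27 proliferation genes were higher (median log2 0.41, camera adjusted p = 0.00103, 0.637 estimated). Ccnb1 (log2 1.05, SE 0.23), Top2a (log2 0.93, SE 0.21) and Mki67 (log2 0.85, SE 0.2) were higher in Bmi1-GFP cells. 1 of 21 stem cell genes was lower (median log2 -0.27, camera adjusted p = 0.058). Its 1 called member was Nkd1 (log2 -3.45, SE 0.37), and Olfm4 was not called (866 ± 237 against 671 ± 81.9 CPM). 6 of 16 immune cell genes were higher and 4 lower (median log2 0.65, camera adjusted p = 0.505). T cell genes Cd8a and Cd96 stood at 54.7 ± 24.5 and 25.5 ± 8.51 CPM in Bmi1-GFP cells and at 0 in enteroendocrine cells, while the myeloid gene Lyz2 (log2 -4.29, SE 0.65, adjusted p = 0.000364) was lower, as were Il1r2 (log2 -8.81, SE 0.99) and Csf2rb (log2 -7.07, SE 0.96). Mcpt1 and Cd209a had no counts in Bmi1-GFP cells (56.6 ± 30.8 and 20.4 ± 10.6 CPM in enteroendocrine cells). In total 3665 genes were called, 1874 higher and 1791 lower, 1201 without enteroendocrine replicate 1. Without that library the calls of Ccnb1, Top2a and Mki67 were lost. The groups were also released with different enzymes.

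Against both lines of Lgr5 stem cells, enteroendocrine cells (n = 2) were higher in hormone and granule genes. Against Lgr5-GFP-Cre (n = 3) the hormone of lowest adjusted p was Ghrl (2280 ± 624 against 20.2 ± 5.15 CPM, log2 6.82, SE 0.44, adjusted p = 2.29e-08), and against Lgr5-GFP-DTR (n = 2) the same gene had log2 7.95 (SE 0.56). Lgr5 was lower against either (38 ± 12.1 against 80.2 ± 13.8 and 101 ± 17.7 CPM, adjusted p = 0.0321 and 0.0161), though both calls were lost without enteroendocrine replicate 1, and 1 each without Lgr5-GFP-Cre replicate 2 and Lgr5-GFP-DTR replicate 1. Cd24a was higher against Lgr5-GFP-Cre (log2 2.56, SE 0.33) and not called against Lgr5-GFP-DTR (1720 ± 37.6 CPM, adjusted p = 0.247).

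With Lgr5-GFP-Cre, 12 of 13 enteroendocrine hormone genes were higher (median log2 4.93, camera adjusted p = 1.71e-15, 0.0313 estimated). Gip had log2 8.22 (SE 0.62), and Nts was not called (adjusted p = 0.672). 15 of 16 secretory granule genes were higher (16 higher and 0 lower by list alone, median log2 4.27, camera adjusted p = 8.21e-18, 0.017 estimated), the median being 3.97 with genes at 0 at their bound. Scg2 and Cpe had log2 5.2 (SE 0.31) and 5.4 (SE 0.37). 15 of 16 enteroendocrine transcription factor genes were higher and 1 lower (median log2 4.87, camera adjusted p = 1.92e-12, 0.101 estimated). Isl1 and Pax6 had log2 6.27 (SE 0.44) and 7.4 (SE 0.56). 16 of 16 tuft genes were higher (median log2 6.89, camera adjusted p = 2.44e-08, 0.327 estimated), the median being 6.7 with genes at 0 at their bound. 13 of 21 stem cell genes were lower (0 higher and 15 lower by list alone, median log2 -1.42, camera adjusted p = 1.25e-07, 0.252 estimated). 22 of 27 proliferation genes were lower (median log2 -1.2, camera adjusted p = 1.59e-11, 0.252 estimated). Ccnb1 and Mcm5 were lower (log2 -2.07, SE 0.24 and log2 -1.99, SE 0.25), and Mki67 was not called (adjusted p = 0.404). Atoh8, Smarcd3 and the laminin gene Lamb3 were lower by the largest amounts (log2 -5.21, SE 0.52, log2 -4, SE 0.77 and log2 -3.99, SE 0.43). The count was 6805 genes, 3779 higher and 3026 lower.

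With Lgr5-GFP-DTR, 12 of 13 enteroendocrine hormone genes were higher (median log2 4.36, camera adjusted p = 6.26e-16, 0.036 estimated). 14 of 16 secretory granule genes were higher (median log2 4.9, camera adjusted p = 3.84e-20, 0.00915 estimated). 15 of 16 enteroendocrine transcription factor genes were higher (15 higher and 1 lower by list alone, median log2 5.53, camera adjusted p = 3.86e-15, 0.0501 estimated). Isl1 had log2 5.89 (SE 0.53), and Pax6 stood at 38.3 ± 18.4 against 0 CPM. For tuft cells, edgeR called 0 of 16 tuft genes, 0 up and 0 down had an unadjusted p under 0.05, and DESeq2 called 0 and 0 (median log2 0.69, camera adjusted p = 0.992), the mean being 0.6 and the test pointing down. 10 of 21 stem cell genes were lower (median log2 -0.88, camera adjusted p = 4.33e-05, 0.429 estimated). 21 of 27 proliferation genes were lower (0 higher and 22 lower by list alone, median log2 -1.04, camera adjusted p = 1.87e-13, 0.183 estimated). Ccnb1 and Cdk1 were lower (log2 -2.29, SE 0.26 and log2 -1.92, SE 0.27). Baiap3, linked to vesicle release, stood at 133 ± 52 against 0 CPM, and Cyp2e1 was lower (log2 -4.13, SE 0.93). The count was 5045 genes, 2947 higher and 2098 lower, and 1896 when fitted on the compared groups only.

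Genes called in Bmi1-GFP against Lgr5-GFP-Cre and in enteroendocrine against Lgr5-GFP-DTR, which share no library, overlapped in the same direction. Both comparisons called 2831 such genes, 1636 higher and 1195 lower, where independent lists of these sizes would share 823 and 471. With Lgr5-GFP-Cre as the control of both the count was 4452 (2541 higher and 1911 lower, beside 1055 and 680 for independent lists). Among genes with an absolute log2 fold change of 1 or more it was 1471. Fold changes correlated at 0.46 with separate controls and 0.65 with the shared one. In 5 simulations of unchanged groups sharing a control the correlation was 0.46 (covariance 0.19, 2.61 in the data). With no gene changed, their 0 shared calls do not bear on the 4452.

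**Figure D3:**
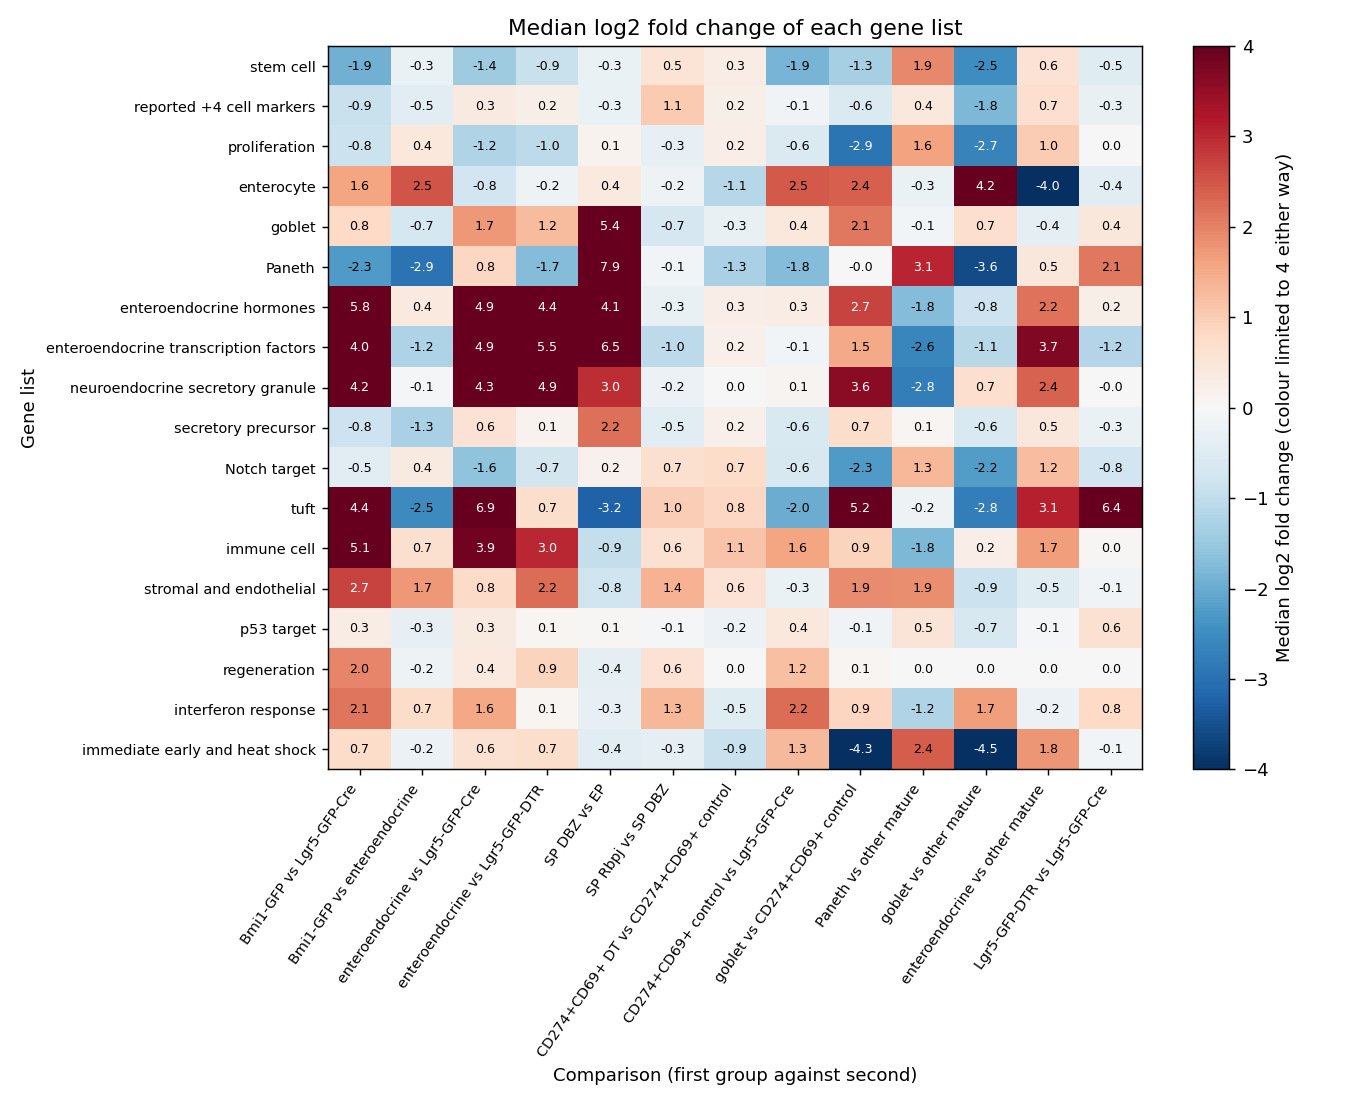
Median log2 fold change of 18 gene lists (vertical) in 13 comparisons (horizontal), as colour limited to 4 in either direction. In Bmi1-GFP against Lgr5-GFP-Cre the medians were 5.75 for enteroendocrine hormones and -1.93 for stem cell genes.

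Between the DTR and Cre lines of Lgr5-GFP, Lgr5 was not called (101 ± 17.7, n = 2, against 80.2 ± 13.8 CPM, n = 3, adjusted p = 0.561). Per the labels the gate was GFP-positive in the DTR line and GFP-high in the Cre line. The matrix protease Mmp7 (2630 ± 1010 against 444 ± 72.3 CPM, log2 2.57, SE 0.43, adjusted p = 0.000645) and the defensin Defa17 (log2 2.23, SE 0.4, adjusted p = 0.00107) were higher in the DTR line. 14 of 15 Paneth genes were higher (15 higher and 0 lower by list alone, median log2 2.1, camera adjusted p = 3.09e-10, 0.174 estimated). Defa21 was the member not called (1700 ± 1310 against 243 ± 167 CPM, adjusted p = 0.0682). 1 of 21 stem cell genes was higher and 4 lower (1 higher and 6 lower by list alone, median log2 -0.49, camera adjusted p = 0.0285, 0.929 estimated). Sp5 and the ion transporter Slc12a2 were lower (log2 -1.19, SE 0.27 and log2 -0.79, SE 0.24), and Olfm4 was not called (adjusted p = 0.386). 3 of 27 proliferation genes were higher and 6 lower (median log2 0, camera adjusted p = 0.767), the mean being -0.1. Mcm2 and Mcm5 were lower (log2 -0.97, SE 0.24 and log2 -0.94, SE 0.23). For enterocytes, edgeR called 0 of 20 enterocyte genes, 1 up and 1 down had an unadjusted p under 0.05, and DESeq2 called 1 and 1 (median log2 -0.43, camera adjusted p = 0.631). Rgs22 and the receptor gene Cd300lf were of greatest difference (log2 8.59, SE 1.21 and log2 7.75, SE 1.09), with Folr1 at 21.9 ± 3.49 against 0 CPM. On the low side stood the growth factor Fgf1 (log2 -5.42, SE 1.3), the clock gene Nr1d1 (log2 -2.6, SE 0.55) and Arhgef10l (log2 -2.57, SE 0.6). Of 3049 genes called, 1408 were higher and 1641 lower. The count was 482 on the compared groups only, where the calls of Sp5, Slc12a2, Mcm2, Mcm5, Fgf1, Nr1d1 and Arhgef10l were lost, and 1928 without Lgr5-GFP-Cre replicate 2. The calls of Sp5, Mcm5, Slc12a2 and Arhgef10l were lost without Lgr5-GFP-DTR replicate 2, and that of Slc12a2 also without Lgr5-GFP-DTR replicate 1 or Lgr5-GFP-Cre replicate 2.

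Atoh1 commits crypt cells to secretory fates and is deleted in the enterocyte progenitors. It stood at 1.56 and 1.81 CPM there and at 60.9 and 125 CPM in crypts 38 h after DBZ (n = 2 each, log2 5.77, SE 0.4, adjusted p = 6.4e-08). DBZ-treated crypts were higher in goblet, Paneth and enteroendocrine genes. The mucus genes Fcgbp (1650 ± 285 against 0.508 ± 0.359 CPM, log2 11.7, SE 0.8, adjusted p = 6.4e-08) and Tff3 (1400 ± 673 against 0.634 ± 0.272 CPM, log2 11.07, SE 0.78, adjusted p = 6.4e-08) and the lectin Zg16 (1380 ± 32.6 against 0.1 ± 0.142 CPM, log2 13.81, SE 1.26, adjusted p = 1.78e-06) were of greatest difference. Without untreated crypts, gains after DBZ cannot be told from losses in deleted, tamoxifen-treated crypts.

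13 of 17 goblet genes were higher (15 higher and 0 lower by list alone, median log2 5.39, camera adjusted p = 6.5e-91, 1.88e-05 estimated). Muc2 had log2 6.23 (SE 0.44), and Tspan13 was not called (adjusted p = 0.0962). 13 of 15 Paneth genes were higher (14 higher and 0 lower by list alone, median log2 7.92, camera adjusted p = 1.3e-60, 0.000283 estimated). Lyz1 stood at 6610 ± 5810 against 27.3 ± 4.74 CPM, and Defa17, Defa24 and Defa21 had log2 8.25 (SE 0.64), 7.95 (SE 0.66) and 10.58 (SE 1.82). The Defa21 call was lost without enterocyte progenitor replicate 1. Clps was not called (157 ± 137 against 202 ± 173 CPM). 13 of 13 enteroendocrine hormone genes were higher (median log2 4.09, camera adjusted p = 1.48e-42, 0.000316 estimated). Ghrl, Chgb and the proglucagon gene Gcg had log2 5.54 (SE 0.59), 4.66 (SE 0.56) and 3.77 (SE 0.5). 13 of 16 enteroendocrine transcription factor genes were higher (14 higher and 0 lower by list alone, median log2 6.55, camera adjusted p = 1.22e-40, 0.000571 estimated), the median being 5.99 with genes at 0 at their bound. Insm1 had log2 7.16 (SE 0.82), Nkx2-2 and Isl1 stood at 6.01 ± 4.82 and 4.68 ± 0.555 CPM beside 0.0159 ± 0.0225 and 0.0318 ± 0.0449 CPM, and St18 was not called. 7 of 13 secretory precursor genes were higher (8 higher and 0 lower by list alone, median log2 2.2, camera adjusted p = 1.75e-21, 0.00806 estimated). The goblet and Paneth regulator Spdef (log2 5.45, SE 0.47, adjusted p = 7.71e-07) and the corepressor Cbfa2t3 (log2 4.37, SE 0.53, adjusted p = 3.88e-05) were higher, and Hes6 was not called (adjusted p = 0.742).

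1 of 21 stem cell genes was higher and 1 lower (1 higher and 3 lower by list alone, median log2 -0.28, camera adjusted p = 0.0447, 0.654 estimated). Tnfrsf19 was higher at a low level (4.33 ± 3.54 against 0.116 ± 0.119 CPM) and Ascl2, the stem cell regulator, lower (19.7 ± 9.84 against 60.5 ± 2.96 CPM, log2 -1.61, SE 0.41, adjusted p = 0.0438), a call lost without either enterocyte progenitor library or DBZ replicate 2. 1 of 9 Notch target genes was lower (median log2 0.17, camera adjusted p = 0.567), the mean being 0.09 and the test pointing down. Notch1 was lower (18 ± 7.43 against 42.7 ± 5.47 CPM, log2 -1.25, SE 0.31, adjusted p = 0.0376), a call lost without the same libraries, and Olfm4 was not called (1140 and 62.8 against 1270 and 1560 CPM). For tuft cells, edgeR called 0 of 16 tuft genes, 0 up and 14 down had an unadjusted p under 0.05, and DESeq2 called 0 and 5 (0 higher and 14 lower by list alone, median log2 -3.23, camera adjusted p = 3.41e-12, 0.165 estimated). Of 20 enterocyte, 27 proliferation, 16 immune cell and 10 stromal genes edgeR called 0 (median log2 0.4, 0.13, -0.95 and -0.81, camera adjusted p = 0.15, 0.504, 0.00259 and 0.5). At an unadjusted p under 0.05 there were 3 enterocyte genes and 1 stromal gene up and 3 immune genes down, and DESeq2 called 1 enterocyte gene up. The immune list had 0.41 estimated. Lower by the largest amounts were the phospholipase gene Pla2g4c (log2 -8.41, SE 2.01), fibronectin, Fn1 (log2 -6.56, SE 1.55), Gkn3 (log2 -5.48, SE 0.68), Matk (log2 -4.02, SE 0.88) and the fucosyltransferase gene Fut2 (log2 -3.83, SE 0.96). All but Gkn3 of these 5 lost their calls without enterocyte progenitor replicate 1 or either DBZ library, and Pla2g4c, Fn1 and Fut2 also without enterocyte progenitor replicate 2. Of 365 genes called, 280 were higher and 85 lower. The count was 142 and 197 without enterocyte progenitor replicates 1 and 2, 188 without DBZ replicate 2, and 657 by DESeq2.

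Rbpj, which encodes the DNA-binding partner of Notch and is deleted per the labels in the other set of secretory progenitors, stood at 22.5 and 29.3 CPM in those crypts and at 40.9 and 33 CPM after DBZ (log2 -0.51, SE 0.2, adjusted p = 0.0747), so these RNA levels do not show the deletion. Crypts labelled as Rbpj-deleted were higher in the stem cell genes Axin2 (105 ± 6.01 against 17.5 ± 1.54 CPM, log2 2.58, SE 0.31, adjusted p = 1.05e-05) and Ephb2 (102 ± 12.9 against 27.8 ± 4.75 CPM, log2 1.87, SE 0.25, adjusted p = 3.46e-05), and lower in Atoh1 (24.7 and 39.4 against 60.9 and 125 CPM, log2 -1.54, SE 0.32, adjusted p = 0.00181), a call lost without DBZ replicate 2. Their libraries were made with another kit, so kit and treatment cannot be told apart here (n = 2 each).

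7 of 21 stem cell genes were higher (median log2 0.54, camera adjusted p = 0.157). Msi1 was higher (log2 3.71, SE 0.66), and Olfm4 was not called (943 ± 97.1 against 599 ± 758 CPM). 2 of 9 Notch target genes were higher (median log2 0.65, camera adjusted p = 0.397). Notch1 and Dtx1 were higher (log2 1.58, SE 0.31 and log2 2.69, SE 0.83). 4 of 13 secretory precursor genes were lower (median log2 -0.46, camera adjusted p = 0.192). Sox4 and Dll3 were lower (log2 -1.22, SE 0.34 and log2 -2.01, SE 0.66), and Dll1 was not called (adjusted p = 0.914). 5 of 17 goblet genes were lower (0 higher and 6 lower by list alone, median log2 -0.67, camera adjusted p = 0.192). Creb3l4, Foxa3 and the disulfide isomerase gene Agr2 were lower (log2 -1.14, SE 0.28, log2 -1.49, SE 0.4 and log2 -1.69, SE 0.46), and Fcgbp was not called (3580 ± 340 against 1650 ± 285 CPM). 1 of 15 Paneth genes was lower (median log2 -0.12, camera adjusted p = 0.653), the called gene being Defa24, and Lyz1 was not called (adjusted p = 0.887). 1 of 20 enterocyte genes was higher (median log2 -0.2, camera adjusted p = 0.868), the called gene being Anpep. Calls were lost without DBZ replicate 2 or Rbpj replicate 1 for Dtx1, Sox4, Dll3, Foxa3, Agr2, Gcg, Sct and Pyy, without Rbpj replicate 1 for Creb3l4, without Rbpj replicate 2 for Dll3, Agr2, Gcg, Sct, Pyy and Anpep, and without DBZ replicate 1 for Dtx1, Defa24 and Anpep. 3 of 13 enteroendocrine hormone genes were lower (median log2 -0.31, camera adjusted p = 0.192): Gcg, Sct and Pyy. Of 16 immune cell and 10 stromal genes edgeR and DESeq2 called 0, with 4 and 1 up at an unadjusted p under 0.05 (median log2 0.6 and 1.4, camera adjusted p = 0.454 and 0.564).

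Lower by the largest amounts in these crypts were histone genes, chosen by size alone: Hist1h1b, Hist1h1e, Hist1h4d and Hist1h2ae had log2 -7.91 (SE 0.62), -7.51 (SE 0.52), -7.2 (SE 0.69) and -5.58 (SE 0.57), followed by H2-Bl (log2 -3.64, SE 1.21). On the high side stood Foxo4 (log2 6.08, SE 0.55), Isoc2a (log2 5.95, SE 0.7), Fn1 (log2 5.75, SE 1.51), Tatdn2 (log2 5.02, SE 0.5) and Mpst (log2 4.95, SE 0.56). Of 3671 genes called, 1907 were higher and 1764 lower. The count was 2072 without DBZ replicate 2 and 1969 without Rbpj replicate 2, and the calls of Fn1 and H2-Bl were lost without either of these or, in turn, without DBZ replicate 1 and Rbpj replicate 1.

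Control cells sorted as CD274+CD69+ (n = 2) were compared with Lgr5-GFP-Cre cells (n = 3). The groups were released with different enzymes, so enzyme and cell type cannot be told apart here, and control replicate 1 is labelled with another kit. The mucus gene Fcgbp (5910 ± 713 against 326 ± 32.2 CPM, log2 4.18, SE 0.48, adjusted p = 2.55e-06) and the sucrase gene Sis (904 ± 10.1 against 53.6 ± 20.4 CPM, log2 4.07, SE 0.53, adjusted p = 1.03e-05) were higher. Lgr5 was lower (22.2 ± 3.73 against 80.2 ± 13.8 CPM, log2 -1.85, SE 0.41, adjusted p = 0.00124). Cd274, which encodes PD-L1, and Cd69 were higher at low levels (2.23 ± 1.05 against 0.911 ± 0.43 and 1.98 ± 2.07 against 0.1 ± 0.138 CPM), calls lost without control replicate 2, and that of Cd274 also without Lgr5-GFP-Cre replicate 1 or 2.

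1 of 21 stem cell genes was higher and 16 lower (1 higher and 17 lower by list alone, median log2 -1.85, camera adjusted p = 3.71e-08, 0.556 estimated). Ascl2, Igfbp4 and Sp5 were lower (log2 -3.79, SE 0.44, log2 -3.46, SE 0.32 and log2 -2.41, SE 0.29). 1 of 9 Notch target genes was higher and 4 lower (median log2 -0.63, camera adjusted p = 0.312). Hes1 and Olfm4 were lower (log2 -1.64, SE 0.38 and log2 -2.66, SE 0.69), Hes5 stood at 0.0715 ± 0.0285 against 1.13 ± 0.485 CPM, and Notch1 was not called. 3 of 27 proliferation genes were higher and 16 lower (median log2 -0.58, camera adjusted p = 0.0054, 0.721 estimated). Cdk1, Pcna and Mcm5 were lower (log2 -1.43, SE 0.25, log2 -1.1, SE 0.2 and log2 -1.24, SE 0.24). 6 of 17 goblet genes were higher and 3 lower (median log2 0.43, camera adjusted p = 0.158). Bcas1 and Clca3 were higher (log2 2.42, SE 0.37 and log2 3.29, SE 0.51), and Spink4 was not called (adjusted p = 0.209). 17 of 20 enterocyte genes were higher (median log2 2.45, camera adjusted p = 1.58e-06, 0.721 estimated). Mttp and Krt20 were higher (log2 3.33, SE 0.4 and log2 4.46, SE 0.58), and Apoa4 was not called (adjusted p = 0.16). 10 of 15 Paneth genes were lower (median log2 -1.75, camera adjusted p = 0.0054, 0.721 estimated). Defa17 and Defa24 were lower (log2 -2.25, SE 0.44 and log2 -2.13, SE 0.47).

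1 of 13 enteroendocrine hormone genes was higher and 2 lower (1 higher and 1 lower by list alone, median log2 0.29, camera adjusted p = 0.966). 2 of 16 enteroendocrine transcription factor genes were higher and 2 lower (median log2 -0.12, camera adjusted p = 0.744). 4 of 13 secretory precursor genes were lower (median log2 -0.62, camera adjusted p = 0.067). 1 of 16 tuft genes was lower (0 higher and 0 lower by list alone, median log2 -1.97, camera adjusted p = 0.0538), and 4 of 16 immune cell genes were higher (3 higher and 0 lower by list alone, median log2 1.58, camera adjusted p = 0.152), the medians being -1.9 and 1.39 with genes at 0 at their bound. Mnx1 was lower (log2 -2.58, SE 0.38), and Chgb and Neurog3 were not called (adjusted p = 0.194 and 0.0592). 7 of 13 immediate early and heat shock genes were higher (median log2 1.29, camera adjusted p = 0.0123, 0.721 estimated). Fosb, Zfp36 and Atf3 were higher (log2 2.7, SE 0.37, log2 1.62, SE 0.29 and log2 1.93, SE 0.38), and Fos was not called (adjusted p = 0.0884). Largest on the high side were Slc37a2 (log2 5.78, SE 0.65), the kinase gene Pim1 (log2 5.3, SE 0.35), the sodium-proton exchanger gene Slc9a3 (log2 5.29, SE 0.48), the enteropeptidase gene Tmprss15 (log2 5.09, SE 0.83) and Cyp1a1, a target of the aryl hydrocarbon receptor (log2 5.02, SE 0.89). On the low side stood Pla2g2a (log2 -6.54, SE 1.5), Cyp2e1 (log2 -5.75, SE 1.03), Gkn3 (log2 -4.83, SE 0.63) and Rgcc (log2 -4.71, SE 0.56). In total 6714 genes were called, 3561 higher and 3153 lower, and 4289 without control replicate 2.

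The same sort 115 h after DBZ, labelled goblet, was compared with the control sort (n = 2 each). The mucin gene Muc2 (5050 ± 319 against 409 ± 6.63 CPM, log2 3.63, SE 0.38, adjusted p = 4.3e-07) and Clca3 (35300 ± 16800 against 948 ± 41.2 CPM, log2 5.22, SE 0.65, adjusted p = 2.71e-06) were higher, and the cyclin gene Ccnb2 (7.85 ± 0.378 against 107 ± 9.59 CPM, log2 -3.77, SE 0.24, adjusted p = 4.08e-09) was lower. Cd274 and Cd69 were not called (adjusted p = 0.248 and 0.333).

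27 of 27 proliferation genes were lower (median log2 -2.93, camera adjusted p = 2.69e-25, 0.119 estimated). Mcm3 and Ccna2 had log2 -3.43 (SE 0.23) and -3.32 (SE 0.24). 1 of 21 stem cell genes was higher and 15 lower (3 higher and 16 lower by list alone, median log2 -1.33, camera adjusted p = 6.7e-05, 0.453 estimated). Smoc2, Cdca7 and Slc12a2 were lower (log2 -5.57, SE 0.34, log2 -4.28, SE 0.35 and log2 -2.67, SE 0.27), and Rnf43 was not called (adjusted p = 0.783). 13 of 17 goblet genes were higher and 1 lower (14 higher and 1 lower by list alone, median log2 2.12, camera adjusted p = 7.11e-05, 0.367 estimated). Sytl2 had log2 3.44 (SE 0.44), and Agr2 was not called (adjusted p = 0.51). 4 of 13 secretory precursor genes were higher and 3 lower (median log2 0.71, camera adjusted p = 0.279). Atoh1 and Spdef were higher (log2 2.48, SE 0.33 and log2 1.94, SE 0.38) and Sox4 lower (log2 -2.3, SE 0.36). 12 of 20 enterocyte genes were higher (median log2 2.39, camera adjusted p = 6.7e-05, 0.479 estimated). Anpep and the peptide transporter Slc15a1 were higher (log2 3.4, SE 0.52 and log2 4.48, SE 0.7). 10 of 13 enteroendocrine hormone genes were higher (11 higher and 0 lower by list alone, median log2 2.69, camera adjusted p = 2.05e-05, 0.307 estimated). Somatostatin, Sst, and Nts were higher (log2 5.24, SE 0.63 and log2 6.61, SE 0.94), as was Iapp at a low level (6.59 ± 0.0596 against 0.103 ± 0.145 CPM). 2 of 15 Paneth genes were higher and 4 lower (median log2 -0.01, camera adjusted p = 0.997), the mean being -0.39 and the test pointing up. Pnliprp2 and the ribonuclease gene Ang4 were higher (log2 5.01, SE 0.89 and log2 3.01, SE 0.77), Defa24 lower (log2 -3, SE 0.52) and Lyz1 not called (4430 ± 1160 against 8740 ± 1320 CPM). 4 of 16 immune cell genes were higher (median log2 0.88, camera adjusted p = 0.122). Ptprc, Cd8a and Cd52 were higher (log2 2.42, SE 0.69, log2 2.88, SE 0.85 and log2 2.26, SE 0.75), calls that were lost without control replicate 1 or goblet replicate 2. Clca6 and Pla2g4c were of greatest difference (log2 9.61, SE 1.14 and log2 9.18, SE 2.08). On the low side stood Olfm4 (log2 -8.05, SE 0.94), the mucosal scavenger gene Dmbt1 (log2 -7.5, SE 0.6), Reg1 (log2 -7.25, SE 0.89), Fgfbp1 (log2 -6.91, SE 0.51) and the water channel gene Aqp8 (0.113 ± 0.0484 against 38.8 ± 1.82 CPM). Of 7603 genes called, 3233 were higher and 4370 lower (42.5% higher), and with DESeq2's size factors, which shifted the median gene by 0.28 log2, 4096 were higher and 3481 lower (54.1% higher).

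Between CD274+CD69+ cells after diphtheria toxin and control cells (n = 2 each), 26 of 14837 genes were called, 11 higher and 15 lower, a count that ranged from 8 to 786 with the processing. The 2 controls, of different kits per the labels, were the closest pair of replicates (Pearson correlation 0.993, chi-square per degree of freedom 4.23 beside 27.8 to 194 in the others), and whether they share a mouse is not given in the sources used here. Both toxin libraries carried Xist, the RNA of X inactivation, at 75.9 and 69.3 CPM (0 and 0.138 CPM in controls) and no counts of the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d (54.6 ± 2.24, 53.3 ± 3.15, 26.8 ± 2.03 and 21.7 ± 2.23 CPM in controls). The other 21 called genes lie on autosomes. Toxin libraries thus carried the female pattern and controls the male one, so sex and toxin cannot be told apart for any gene or list of this comparison. The labels give both groups as wild type and do not give the source of toxin sensitivity.

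Among called autosomal genes the kinase gene Pim1 (8.06 and 7.92 against 122 and 113 CPM, log2 -3.87, SE 0.38, adjusted p = 1.81e-05), the transporter Slc37a2 (1.27 and 5.39 against 72.5 and 73.6 CPM, log2 -4.46, SE 0.71, adjusted p = 0.00771) and Cyp1a1 (0.164 and 0.291 against 82.9 and 84.8 CPM, log2 -8.51, SE 1.32, adjusted p = 0.00771) fell. Ppic, Gng11, the phosphate transporter gene Slc34a2 and the Wnt inhibitor gene Sfrp5 fell by less (log2 -1.87, SE 0.23, log2 -2.23, SE 0.34, log2 -3.1, SE 0.53 and log2 -2.21, SE 0.38). Glo1, Cyp4f16 and Fras1 fell too (log2 -0.99, SE 0.18, log2 -1.63, SE 0.33 and log2 -4.08, SE 0.75), as did Gif (0 and 0.0971 against 3.18 and 7.98 CPM). On the other side the molybdenum cofactor gene Mocs1 (71.8 and 92.1 against 5.5 and 4.54 CPM, log2 4.03, SE 0.59, adjusted p = 0.00388), the sorting receptor Sorl1 (76.9 and 128 against 26.2 and 25.9 CPM, log2 1.97, SE 0.34, adjusted p = 0.0166) and Clu (7.53 and 5.88 against 0.925 and 0.642 CPM, log2 3.09, SE 0.54, adjusted p = 0.0167), clusterin, rose. Igfbp4, B3galt5, Paqr5, Igj, Tmem173 and Fut2 rose as well (log2 1.72, SE 0.31, log2 3.36, SE 0.63, log2 4.39, SE 0.82, log2 6.15, SE 1.13, log2 2.08, SE 0.39 and log2 5.6, SE 1.09), Fut2 standing at 57.2 and 4.32 CPM in the 2 toxin libraries. Cd274 and Cd69 were not called (adjusted p = 0.986 and 1). The 26 calls fell to 8 without either control, where those of Mocs1, Igfbp4, Clu, B3galt5, Fut2 and Igj were among the lost, and to 11 and 15 without toxin replicates 1 and 2, where Cyp1a1, Clu and B3galt5 were. Reg3b and Reg3g, antimicrobial lectins chosen after their values were seen, were not called either, at 15900 and 12900 against 889 and 798 CPM (log2 4.09, SE 1.13, adjusted p = 0.239) and at 10000 and 7090 against 1490 and 1360 CPM (adjusted p = 0.613).

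1 of 21 stem cell genes was higher (median log2 0.29, camera adjusted p = 0.027, 0.662 estimated). Olfm4 stood at 717 ± 69.4 against 783 ± 1.02 CPM. For the cell cycle, edgeR called 0 of 27 proliferation genes, 1 up and 0 down had an unadjusted p under 0.05, and DESeq2 called 0 and 0 (median log2 0.25, camera adjusted p = 0.00243, 0.662 estimated). For enterocytes, edgeR called 0 of 20 enterocyte genes, 0 up and 8 down had an unadjusted p under 0.05, and DESeq2 called 0 and 1 (0 higher and 1 lower by list alone, median log2 -1.13, camera adjusted p = 1.39e-12, 0.221 estimated). For Paneth cells, edgeR called 0 of 15 Paneth genes, 0 up and 7 down had an unadjusted p under 0.05, and DESeq2 called 0 and 1 (0 higher and 4 lower by list alone, median log2 -1.31, camera adjusted p = 3.49e-08, 0.221 estimated). Lyz1 stood at 4780 ± 903 against 8740 ± 1320 CPM. For goblet cells, edgeR called 0 of 17 goblet genes, 1 up and 1 down had an unadjusted p under 0.05, and DESeq2 called 1 and 0 (1 higher and 0 lower by list alone, median log2 -0.3, camera adjusted p = 0.073), the mean being 0.17. Among hormone and precursor genes edgeR called 0 of 13 and 0 of 13, 1 up and 1 down and then 0 had an unadjusted p under 0.05, and DESeq2 called 1 up in the first list and 0 in the other (median log2 0.27 and 0.2, camera adjusted p = 0.409 and 0.232). By list alone, 1 hormone gene was higher. 1 of 11 regeneration genes was higher (2 higher and 2 lower by list alone, median log2 0.02, camera adjusted p = 0.987), the mean being 0.4, the test pointing down and the median 0 with genes at 0 at their bound. Of 13 interferon response, 16 p53 target, 16 immune cell and 13 immediate early genes edgeR called 0, and 0 up and 1, 0, 0 and 6 down by list alone. At an unadjusted p under 0.05 there were 4, 4, 0 and 8 down and 2 immune genes up, and DESeq2 called 1, 0, 0 and 1 down. Their medians were -0.48, -0.25, 1.13 and -0.88 (camera adjusted p = 1.65e-05, 0.119, 1.12e-06 and 1.85e-10). The interferon, immune and immediate early lists had 0.221, 0.221 and 0.12 estimated. Jun stood at 999 ± 297 against 1840 ± 5.1 CPM (adjusted p = 0.574).

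For a stem to goblet axis, 200 genes per direction were taken from Lgr5-GFP-Cre and goblet cells, which share no library with this comparison. Genes higher in stem cells had a median log2 fold change of 0.22 after toxin and 90% of them were higher, with 0 called up and 1 down by edgeR, 18 up and 2 down at an unadjusted p under 0.05 and 0 up and 1 down by DESeq2 (camera p = 2.09e-11, p = 0.229 with an estimated correlation). Genes higher in goblet cells had a median of -0.16 and 20.5% were higher, with 0 called by edgeR, 3 up and 21 down at an unadjusted p under 0.05 and 2 up and 0 down by DESeq2 (camera p = 1.42e-07, p = 0.136 with an estimated correlation). The median of the first list was 0.09 without toxin replicate 1 and that of the other -0.29 without toxin replicate 2. Sex and toxin cannot be told apart on this axis either. The count of 26 called genes was 10 with the kit as a covariate, 56 with no filter and 127 by DESeq2. On the compared groups only it was 425, or 786 (226 higher and 560 lower) with a replicate block too. With the kit as a covariate 5 autosomal genes stayed called (Pim1, Ppic, Slc37a2, Cyp1a1 and Gif) and 16 did not.

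A single Bmi1-GFP library from a mouse irradiated with 10 Gy and taken at 36 h was described against the 3 unirradiated libraries, without a test. Enterocyte genes stood higher, with the apolipoprotein gene Apoa1 (30300 against 2510 ± 1330 CPM), and genes of the cell cycle lower, with Mki67 (9.5 against 157 ± 11.3 CPM). Bmi1 stood within the range of the controls (27 against 25.1 ± 2.87 CPM), and Lgr5 (1.49 against 21.5 ± 3.2 CPM) and Olfm4 (15.4 against 885 ± 234 CPM) stood below theirs. Of 14410 genes, 4538 lay outside the range by more than 1 on the log2 scale, 1757 above and 2781 below, and the median gene lay at -0.18.

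Enterocyte genes (20 of 20 above and 0 below these limits, median log2 ratio 3.27, percentile 100) included Fabp1 (18700 against 2460 ± 875 CPM) and Fabp2 (19700 against 2430 ± 1590 CPM), fatty acid binding proteins. Regeneration genes (7 of 10 above and 1 below these limits, median log2 ratio 2.83, percentile 100) included the growth factor Areg (603 against 93.5 ± 20 CPM) and S100a6 (129 against 17.6 ± 7.35 CPM). Targets of p53 (9 of 16 above and 0 below these limits, median log2 ratio 1.34, percentile 100) included the cyclin Ccng1 (351 against 72.8 ± 14.3 CPM) and Perp (619 against 206 ± 41.1 CPM), while Cdkn1a (408 against 259 ± 57.2 CPM) did not pass them. Chosen after their values were seen, Mdm2 (141 against 55 ± 3.92 CPM), Phlda3 (29.6 against 0.947 ± 0.454 CPM), Eda2r (11.8 against 0.535 ± 0.336 CPM), Clu (29.2 against 6.55 ± 2.64 CPM), Reg3b (28700 against 1200 ± 306 CPM) and Reg3g (10100 against 1150 ± 362 CPM) lay above them, and Ly6a (17.3 against 7.58 ± 3.39 CPM) and Chga (317 against 1420 ± 819 CPM) did not pass them. Interferon response genes (6 of 13 above and 0 below these limits, median log2 ratio 1.25, percentile 100) included Oasl2 (180 against 48.6 ± 3.96 CPM). On the low side were proliferation genes (0 of 27 above and 25 below these limits, median log2 ratio -3.23, percentile 0), among them Mcm6 (33.2 against 148 ± 27.2 CPM), and stem cell genes (1 of 21 above and 10 below these limits, median log2 ratio -1.42, percentile 0), among them Slc12a2 (75.6 against 308 ± 42.3 CPM). Endocrine genes lay lower, both hormones (0 of 13 above and 6 below these limits, median log2 ratio -1.92, percentile 0) and transcription factors (0 of 16 above and 14 below these limits, median log2 ratio -2.79, percentile 0). Examples are Ghrl (393 against 2720 ± 297 CPM), Cck (324 against 2330 ± 359 CPM) and Isl1 (3.47 against 44.8 ± 15.5 CPM). Immune cell genes (0 of 16 above and 14 below these limits, median log2 ratio -2.46, percentile 0) included Gzma (137 against 741 ± 353 CPM). Paneth genes (0 of 15 above and 5 below these limits, median log2 ratio -1.04, percentile 0.1) included Ang4 (156 against 867 ± 394 CPM). Goblet genes (5 of 17 above and 3 below these limits, median log2 ratio -0.17, percentile 15.2) went both ways, with Fcgbp (4830 against 1170 ± 528 CPM) and Zg16 (5720 against 681 ± 485 CPM) above. Early response genes (1 of 13 above and 1 below these limits, median log2 ratio 0.15, percentile 16.1) included Fos (2430 against 1230 ± 255 CPM), which did not pass them.

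Of greatest rise in the irradiated library were the lectin Mbl2 (514 against 3.61 ± 2.25 CPM), Tmprss15 (225 against 4.74 ± 5.51 CPM) and the alkaline phosphatase Akp3 (1750 against 44.3 ± 39.9 CPM), with Gkn1 and Gkn2, stomach peptides, at 61.9 and 49.1 CPM. Igj, Gsdmc2 and Prelp stood at 0 CPM there (136 ± 46.7, 53.6 ± 51.2 and 31.1 ± 8.64 CPM in controls), and Gsdmc4 (0.359 against 108 ± 83.8 CPM) was low. Of 199 genes higher in Lgr5-GFP-DTR than in enteroendocrine cells, chosen without these libraries, the median log2 ratio was -0.39 (percentile 0 of random lists), and of 199 genes higher in enteroendocrine cells it was -0.74 (percentile 0). With DESeq2's size factors the first was -0.3, and with 50 genes per list the medians were -0.61 and -1.99.

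**Figure D4:**
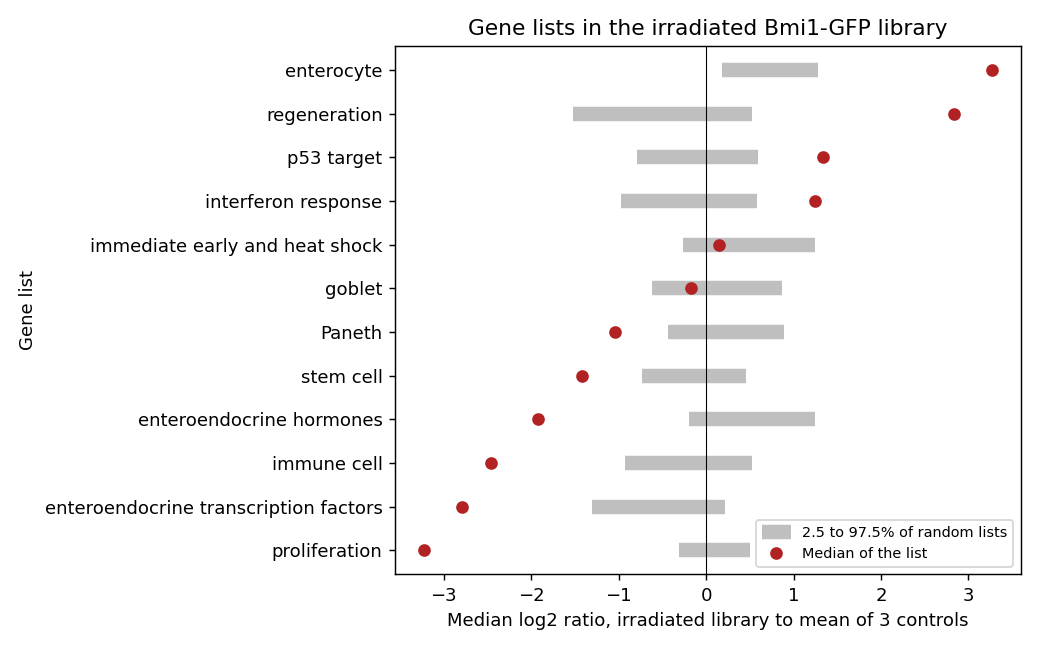
Median log2 ratio of 12 gene lists in the irradiated Bmi1-GFP library (n = 1) relative to the mean of 3 unirradiated libraries (points), with the central 95% of random lists matched on expression (grey bars). Proliferation genes had a median of -3.23 and enterocyte genes of 3.27.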

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

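The tests below on sex, background, dilution and radiation, and the use of the planned kit covariate to test the kit, were chosen only after the results were seen, while those on the spread of the implied Paneth share, on scaling and on splits of the samples were planned.

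Between CD274+CD69+ toxin and control cells, 26 genes were called (8 without either control, 11 and 15 without toxin replicates 1 and 2). On X and Y, 5 called genes carried the female pattern in both toxin libraries and the male pattern in both controls, in line with mice of different sex, and for the 21 autosomal genes sex and toxin cannot be told apart. Of the autosomal genes, 6 pairs lay within 10 Mb beside a mean of 2.22 in 10000 random draws (one-sided permutation p = 0.0347), which is consistent with linked differences in genetic background, with 3 pairs on chromosome 17 (Pim1, Glo1 and Cyp4f16), 2 on 9 and 1 on 5. With the kit as a covariate 5 autosomal genes stayed called, and 3 (Pim1, Ppic and Cyp1a1) also without control replicate 1, which argues against its kit as the whole cause for these 3, with control replicate 2 the lone control in effect and taken to vary like the other groups. The other 18 lost their call in at least 1 of these fits as the SE grew, while their fold kept its size. Their median absolute log2 was 3.23 (SE 0.57) before and 3.42 (SE 0.77) with the covariate. The latter rests on control replicate 2, labelled with the kit of the toxin libraries. That is 1 library, and the genes were selected from both controls, so the kit stays unsettled for them. A response to toxin stays open.

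In the irradiated library enterocyte genes stood high and proliferation genes low. An admixture of enterocytes alone would lower the genes of all other cells alike. Instead the goblet median exceeded the proliferation median by 3.06 log2 (SD 0.05 among the 3 controls). Goblet genes had the smallest fall of the lists with a negative median (-0.17), beside -1.04 for Paneth, -1.92 for hormone and -2.46 for immune cell genes. Falls this unequal argue against enterocytes alone as the whole cause. An admixture that also held goblet cells could leave the same gap and was not tested. Targets of p53 had a median of 1.34, a value that could follow from radiation of whichever cells were sorted, so a response of the Bmi1-GFP cells cannot be told apart from a change in the cells in the gate with 1 library.

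Of 15 listed Paneth genes, 14 were called higher in Lgr5-GFP-DTR than in Lgr5-GFP-Cre cells (camera adjusted p 0.174 with an estimated correlation), and the share of Paneth RNA they implied had a median of 64.5% with a ratio of 2.38 between its 75th and 25th percentiles, which Paneth cells or their RNA in the GFP-positive gate could give in part. Shares of up to 113% (Defa3) cannot be literal, and Lgr5, at 98.3 CPM in Paneth libraries too, does not separate the cells. Without the 20 most abundant genes the median of the remaining 11 Paneth genes was 2.14 beside 2.23. TMM trims such genes anyway, so scaling stays open. The tuft cell gene Dclk1 stood at 284 and 417 CPM beside 2.07 to 3.67 CPM, so more than 1 cell type may differ between the gates.

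For Bmi1-GFP against Lgr5-GFP-Cre, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 7475 called genes, and the highest of the others gave 0. With 10 splits the share is never under 0.05.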

How the results depend on the processing

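The count without genes on the X and Y chromosomes and the centred ratios of the irradiated library were chosen only after the results were seen. Counts of called genes with an absolute log2 fold change of 1 or more were 4372 for Bmi1-GFP against Lgr5-GFP-Cre, 2292 for Bmi1-GFP against enteroendocrine, 4416 and 3350 for enteroendocrine against Lgr5-GFP-Cre and Lgr5-GFP-DTR, 2124 for Rbpj against DBZ, 4326 for CD274+CD69+ control against Lgr5-GFP-Cre, 2901 for Paneth against the other mature cells and 1830 for Lgr5-GFP-DTR against Lgr5-GFP-Cre. On the compared groups only, the counts were 1896 for enteroendocrine against Lgr5-GFP-DTR, 425 for toxin against control and 482 for Lgr5-GFP-DTR against Lgr5-GFP-Cre. DESeq2 called 657 genes for DBZ against enterocyte progenitors and 127 for toxin against control. Toxin against control gave 56 genes with no filter, 10 with the kit as a covariate and 21 without X and Y genes. The overlap of Bmi1-GFP and enteroendocrine calls was 4452 with the shared control and 1471 at an absolute log2 fold change of 1 or more. With an estimated correlation 11 gene lists passed instead of 62, and the toxin medians of 0.22 and -0.16 had p = 0.229 and p = 0.136. In the irradiated library genes higher in stem than in enteroendocrine cells had a median of -0.3 with DESeq2's size factors and -0.61 with 50 genes, those higher in enteroendocrine cells -1.99 with 50 genes, and 4593 genes lay outside the range after centring. Of other gene and list values, called or not, 4323 kept direction and side of the threshold. Of the rest, 200 fell short, 70 newly passed, 13 irradiated ones moved and 1 turned. That was Lyz1 in Rbpj against DBZ, at log2 1.21 and -0.82 without DBZ replicates 1 and 2 (-0.12 in full). Of 316 calls of named genes, 242 held in all settings. The cause of these differences was not tested.

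With 1 library left out at a time, the counts ranged from 6179 to 7260 (Bmi1-GFP against Lgr5-GFP-Cre), 1201 to 2926 (against enteroendocrine), 4807 to 6333 and 3384 to 4611 (enteroendocrine against Lgr5-GFP-Cre and Lgr5-GFP-DTR), 142 to 447 (DBZ against enterocyte progenitors), 1969 to 3019 (Rbpj against DBZ), 8 to 15 (toxin against control), 4289 to 6666 (CD274+CD69+ control against Lgr5-GFP-Cre), 5710 to 6129 (goblet against control), 3623 to 4749, 7347 to 8793 and 5923 to 8051 (Paneth, goblet and enteroendocrine against the others), 1928 to 3514 (Lgr5-GFP-DTR against Lgr5-GFP-Cre) and 4667 to 5421 (irradiated).

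A replicate block, on the compared groups only, gave 1241 calls for Bmi1-GFP against enteroendocrine and 3577 and 1184 for enteroendocrine against Lgr5-GFP-Cre and Lgr5-GFP-DTR. It gave 219 for DBZ against enterocyte progenitors, 2399 for Rbpj against DBZ, 786 for toxin against control and 475 for Lgr5-GFP-DTR against Lgr5-GFP-Cre. Fit and block thus both bear on these counts. After group means were removed, libraries of the same number correlated at -0.07, 0.01 and 0.05 in Bmi1-GFP and Lgr5-GFP-Cre and at 0.13 and 0.13 in toxin and control, the range over all comparisons being -0.07 to 0.13, and whether the numbers pair libraries was left open.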

Other observations

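Both paragraphs describe lists or genes chosen only after their values were seen. Tuft cell genes varied between sorts that are not named for them. In Lgr5-GFP-DTR against Lgr5-GFP-Cre cells 16 of 16 tuft genes were higher (median log2 6.38, camera adjusted p = 1.13e-19, 0.174 estimated), among them Dclk1, a tuft cell kinase (log2 7, SE 1.04, adjusted p = 0.000285). In goblet cells against the control CD274+CD69+ sort 14 of 16 were higher (15 by list alone, median log2 5.2, camera adjusted p = 9.62e-05, 0.479 estimated). Enterocyte progenitor crypts held Dclk1 at 445 and 221 CPM beside 43 and 30.3 CPM after DBZ, a difference that was not called (adjusted p = 0.125).

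Immediate early genes were lower in goblet cells than in the control sort, 13 of 13 (median log2 -4.28, camera adjusted p = 8.45e-08, 0.119 estimated), and higher in Paneth cells than in the other mature cells, 11 of 13 (median log2 2.41, camera adjusted p = 2.8e-08, 0.0916 estimated). Immune cell genes were higher in enteroendocrine cells than in Lgr5-GFP-Cre cells, 13 of 16 (14 by list alone, 1 lower, median log2 3.86, camera adjusted p = 4.24e-06, 0.274 estimated), and than in Lgr5-GFP-DTR cells, 11 of 16 (12 by list alone, 1 lower, median log2 3.02, camera adjusted p = 3.5e-05, 0.4 estimated). Interferon response genes were higher in Bmi1-GFP than in Lgr5-GFP-Cre cells, 10 of 13 (median log2 2.15, camera adjusted p = 4.78e-06, 0.152 estimated). Enterocyte genes were higher in Bmi1-GFP than in enteroendocrine cells, 19 of 20 (median log2 2.52, camera adjusted p = 1.51e-11, 0.637 estimated), and than in Lgr5-GFP-Cre cells, 16 of 20 (17 by list alone, median log2 1.57, camera adjusted p = 0.00014, 0.458 estimated). In Paneth cells against the other mature cells 26 of 27 proliferation genes were higher (median log2 1.62, camera adjusted p = 1.07e-26, 0.0517 estimated), as were 16 of 21 stem cell genes (median log2 1.93, camera adjusted p = 3.16e-13, 0.0916 estimated).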
